A study of Mus musculus with 3 samples.

How the data were processed

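The 3 libraries were droplet single-cell RNA libraries (10x Genomics Chromium): 1 of Achilles tendon after sural neurectomy, 1 of Achilles tendon after a sham operation and 1 of dorsal root ganglia (DRG). Per the labels' protocols, tendon was digested with collagenases and dispase and its red cells were lysed, and ganglia were digested with papain, collagenase and dispase and enriched on a density medium, which removes debris and small cells and can set the shares of classes. The deposited values are whole UMI counts per gene and barcode, not normalized. They were made with Cell Ranger 8.0.1, per the file headers, and the submitters' processing notes name Cell Ranger and the builds mm10 and GRCm39 without saying which was used for which library, so no coordinates are given. The aligner settings and the annotation release are not given in the sources used here. The tendon files give 33696 features with Ensembl identifiers, of which 52 share a symbol with another feature, and the DRG file gives 35980 features by symbol only, including 4 vector features. The deposited barcodes start at 516, 500 and 501 UMIs in the neurectomy, sham and DRG libraries, and their medians of 1212, 1065 and 3422 UMIs limit the precision of values per barcode. Barcodes with at least 5000 UMIs were 11.8%, 16.1% and 34.1% of the barcodes and held 61.5%, 75.4% and 83.7% of the UMIs.

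Barcodes were kept with at least 500 genes and at most 15% mitochondrial UMIs. This left 21992, 25306 and 22384 barcodes, with 2962, 7523 and 825 barcodes left out for few genes and 113, 122 and 357 others for mitochondrial UMIs. Doublets were scored with Scrublet as implemented in scanpy. Its automatic threshold marked 2.75% of the DRG barcodes, which were removed, and 0% in both tendon libraries, so the caller did not work there and the barcodes in the top 8% by score were removed instead. Those removed had median depths of 1118 and 1079 UMIs in the neurectomy and sham libraries, under the 1347.5 and 1338 of all barcodes that passed, so they were not the deep barcodes that doublets would give, and doublets remain among the tendon barcodes. The barcodes analysed numbered 20149, 23176 and 21768.

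Both tendon libraries were clustered together without integration, and the DRG library alone. Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at resolution 1. Vector features stayed out of the variable genes. The neuron barcodes were clustered again in the same way. Clusters were named from markers of 27 tendon classes, 21 DRG classes and 8 neuron subtypes. Folds were taken over the median of the clusters after adding 10 CPM. A name needed at least 3 markers at 2-fold, a mean log2 fold of the markers of at least 1, a lead of 0.5 over the next class, and a marker among the top 10 genes by fold unless the mean was at least 3. A cluster stayed unnamed where markers of another class outnumbered its own among those genes, or did not fall short of them where its median depth was under 1/3 of the library's. In the tendon libraries 11 of 37 clusters stayed unnamed, in the DRG library 2 of 33 and among the neurons 14 of 30. The markers were fixed in advance, but these thresholds were set after the clusters had been seen. The lead, the need for a leading marker and the lowest mean kept 7 tendon clusters out of the class they scored nearest: cluster 27 out of the tenocyte class (0.00993% of the neurectomy and 0.971% of the sham barcodes), clusters 4, 19 and 22 out of the stromal fibroblast class (10.7% and 3.24%, 2.54% and 0.0431%, 1.45% and 0.470%), clusters 17 and 25 out of the lymphatic class (0.104% and 3.47%, 1.48% and 0.00431%) and cluster 35 out of the proliferating class (0.199% and 0%). At 5000 UMIs the lead kept out clusters nearest to the tenocyte class (4.04% and 4.32%), the Pi16 class (18.6% and 9.50%), the stromal fibroblast class (9.25% and 5.08%), the lymphatic class (1.58% and 5.63%) and the dendritic class (0.788% and 1.35%), and the need for a leading marker kept out a cluster nearest to T and NK cells (0.205% and 0.324%). For neuron sub-clusters, markers of the other DRG classes among the top genes also counted against a name unless they led 4 or more sub-clusters, a rule added after those had been seen, which kept 5 of them, with 212 neurons (6.11%), out of a subtype. Several unnamed tendon clusters came almost wholly from 1 library and may be that library rather than a cell type.

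Raw UMIs were summed per class and library and scaled to the class total (CPM). Classes with at least 100 barcodes in each library were compared. A gene entered with a summed count of at least 50 and at least 10 CPM in the higher library. Ratios have exact conditional 95% intervals, counts exact Poisson intervals and shares exact Clopper-Pearson intervals, all for counting error only, and a level of 0 is set against 3 counts. With 1 library per group no test between groups was possible. Genes were named by a rule fixed before the data were examined. It took, among genes not mitochondrial, ribosomal, haemoglobin, sex-linked or unnamed models, with an interval wholly beyond 1.5-fold and the same direction under the other scalings, the 12 highest and 12 lowest log2 ratios in the tenocyte class and the 6 highest and 6 lowest in each other class, and any member of the fixed lists. Sfrp4 in the Pi16 fibroblast class and Inhba in the lymphatic class come from those lists. The median ratio of all genes moved by under 0.1 on the log2 scale under each other scaling.

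Gene lists were fixed in number at 33, with 594 genes, and those reported are the FGF ligands, FGF receptors, FGF feedback and target genes, tenogenic genes, fibrillar collagen and tendon matrix, inflammatory cytokines and mediators, interferon response, antigen presentation, cell cycle, hypoxia and glycolysis, apoptosis, unfolded protein response, Wnt pathway, stress and immediate-early genes, endothelial activation and angiogenesis, and for the neurons the neuropeptides, growth factors, sensory ion channels and receptors and nerve injury genes. A median needed at least 3 members that entered and was set against 10000 random lists of the same size matched on mean expression. Outside the tenocyte class, medians are reported for the FGF feedback, interferon, inflammatory, cell cycle, tenogenic and matrix lists in each class, and for endothelial activation and angiogenesis in the endothelial-like class. The other medians outside the tenocyte class were computed and left out to keep the text short, a choice made after they were seen, and of these the mural-like antigen presentation median turned direction under an alternative. To compare shares of barcodes with a UMI across depths, each barcode was thinned to 2000 UMIs and shallower ones were left out. Neurons with at least 1 UMI of the vector feature AAV_gene1 were called traced. The labels do not say that this feature is the injected reporter.

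The steps were tested on simulated data drawn from the tenocyte class of both libraries with 8203 genes, 50 each made 1.5, 2, 4 and 8-fold apart. The 95% intervals held the true ratio for 98%, 98%, 100% and 96% of them and for 95.3% of the 8003 unchanged genes. Intervals lay wholly beyond 1.5-fold for 21, 49, 50 and 50 of them and for 0 unchanged genes. All 24 genes picked by the naming rule were truly changed, a list made 2-fold apart lay at percentile 100 and 4 of 100 unchanged lists lay outside the central 95% of random lists. The simulated counts had only Poisson error around a shared profile, the error that the intervals assume, and no differences between mice. They check the computation and do not give the rate of false calls in these libraries. Inside the sham library 363 of 8477 genes had intervals beyond 1.5-fold between Y-only and Xist-only tenocyte barcodes at equal UMIs. In advance 34 alternatives were listed (other scalings, filters, doublet handling, resolution, thinning depth and tracer threshold), and 12 were added after seeing the data, which restrict depth, leave genes out of the clustering, add unnamed clusters to the nearest class or match the sex type of sham barcodes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9. Seeds were fixed.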

Results

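The series concerns sensory nerves, fibroblast growth factor 1 (FGF1) and FGF receptors in degeneration of mouse tendon. Droplet single-cell RNA sequencing (10x Genomics Chromium), in which each captured transcript carries a unique molecular identifier (UMI) and each droplet a barcode, was run on 3 libraries from C57BL/6 mice. The neurectomy library came from Achilles tendon of mice whose sural nerve, a sensory nerve of the hind limb, was cut 1 week before 4 weeks of immobilisation with the ankle dorsiflexed. The sham library came from Achilles tendon after a sham operation and the same 4 weeks of immobilisation. The labels give 5 mice for each tendon group and do not say how they were combined. The DRG library held lumbar and sacral dorsal root ganglia, which contain the cell bodies of sensory neurons, taken 4 weeks after 5 µL of an adeno-associated virus carrying a fluorescent reporter was injected into the sheath of the left Achilles tendon, and 18 ganglia of 6 mice were pooled. The labels differ on whether the ganglia came from the injected side alone or from both sides, and 1 label calls the vector a lentivirus. There was 1 library per group, so no difference between groups had a replicate check and no p-value is given. Intervals are exact 95% intervals (Poisson for counts, Clopper-Pearson for shares, conditional binomial for ratios) and cover counting error only.

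The neurectomy library held 25067 barcodes and 79750679 UMIs, with a median of 1212 UMIs per barcode. The sham library held 32951 barcodes and 133570956 UMIs, with a median of 1065. The DRG library held 23566 barcodes and 239515477 UMIs, with a median of 3422. After filters on genes, mitochondrial UMIs and doublets, 20149, 23176 and 21768 barcodes remained in the neurectomy, sham and DRG libraries. Transcripts of the sex chromosomes, read as a check of the pools, differed between the libraries. The sum of 4 Y-linked genes was 39 UMIs in the neurectomy library, 6366 in the sham library and 49538 in the DRG library, whereas Xist, the transcript that silences an X chromosome in female cells, had 55528, 61571 and 23 UMIs. Among barcodes with at least 5000 UMIs, 19.4% (18.3 to 20.5%) of the sham library and 0 of 2920 in the neurectomy library (upper bound 0.126%) held a Y-linked UMI without Xist. Every comparison of the tendon libraries therefore also compared a pool of female type with a pool of mixed type.

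The cell classes of tendon were compared to ask how its makeup differed between denervated and sham-operated limbs. Tenocyte-like barcodes, the collagen-producing cells of tendon, were 9.15% (8.76 to 9.56%) of the neurectomy library and 31.2% (30.6 to 31.8%) of the sham library, a ratio of 0.293 (0.278 to 0.308). Proliferating barcodes, led by mitotic genes such as Mki67, were 5.80% against 1.14%, a ratio of 5.09 (4.45 to 5.84). Schwann-like barcodes, the glia that wrap peripheral axons, were 2.26% against 0.790%, a ratio of 2.86 (2.40 to 3.41). Endothelial-like barcodes (ratio 1.81, 1.61 to 2.03) and lymphatic endothelial-like barcodes (1.23, 1.15 to 1.32) made up more of the neurectomy library, and mural-like barcodes, the contractile cells around vessels, made up less of it (0.648, 0.574 to 0.731). Fibroblast-like barcodes marked by Pi16, a gene of the connective-tissue layers around organs and vessels, were 20.3% against 13.6%, a ratio of 1.49 (1.42 to 1.56). Macrophage-like barcodes were 11.3% against 10.5%, a ratio of 1.07 (1.01 to 1.14). Skeletal muscle-like barcodes numbered 259 of the neurectomy library and 19 of the sham library, a ratio of 15.7 (9.84 to 26.5), so the libraries differed in muscle-like barcodes. Clusters left without a name held 29.9% of the neurectomy barcodes and 21.5% of the sham barcodes.

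The share ratios moved with depth. Among barcodes with at least 5000 UMIs, clustered anew as an alternative chosen after seeing the data, the tenocyte ratio was 0.770 (0.707 to 0.839), with at least 1000 genes per barcode it was 0.545, and the Pi16 ratio turned to 0.646 and 0.577 under those settings and to 0.658 at Leiden resolution 2, although at 5000 UMIs a cluster nearest to the Pi16 class, with 18.6% of the neurectomy and 9.50% of the sham barcodes, stayed unnamed. With the clusters that the naming thresholds left out added to the class they scored nearest, another alternative chosen after seeing the data, the lymphatic ratio was 0.954 (0.897 to 1.01), and at 5000 UMIs 0.717 (0.597 to 0.857), so its direction rested on those thresholds. The cluster added to it at 5000 UMIs scored 2.501 for lymphatic and 2.495 for tenocyte markers. Of its 296 sham barcodes 86 (29.1%) held both Xist and a Y-linked UMI, against 5.29% of all sham barcodes, so it may hold doublets. With the clusters added, the Pi16 ratio at 5000 UMIs was 1.40 and the tenocyte ratio 0.284 over all barcodes and 0.789 at 5000 UMIs. The cluster added to the Pi16 class there scored 2.315 for Pi16 and 2.276 for stromal fibroblast markers. Clusters led by genes of another class were not added. Of these, a cluster nearest to tenocytes held 3.68% of the neurectomy and 2.32% of the sham barcodes, and another at 5000 UMIs 3.63% and 1.96%. The macrophage ratio turned to 0.924 when doublets were kept, and the synovial lining-like ratio of 2.02 (1.65 to 2.49) turned to 0.784 there and to 0.623 with at most 5% mitochondrial UMIs.

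**Figure D1:**
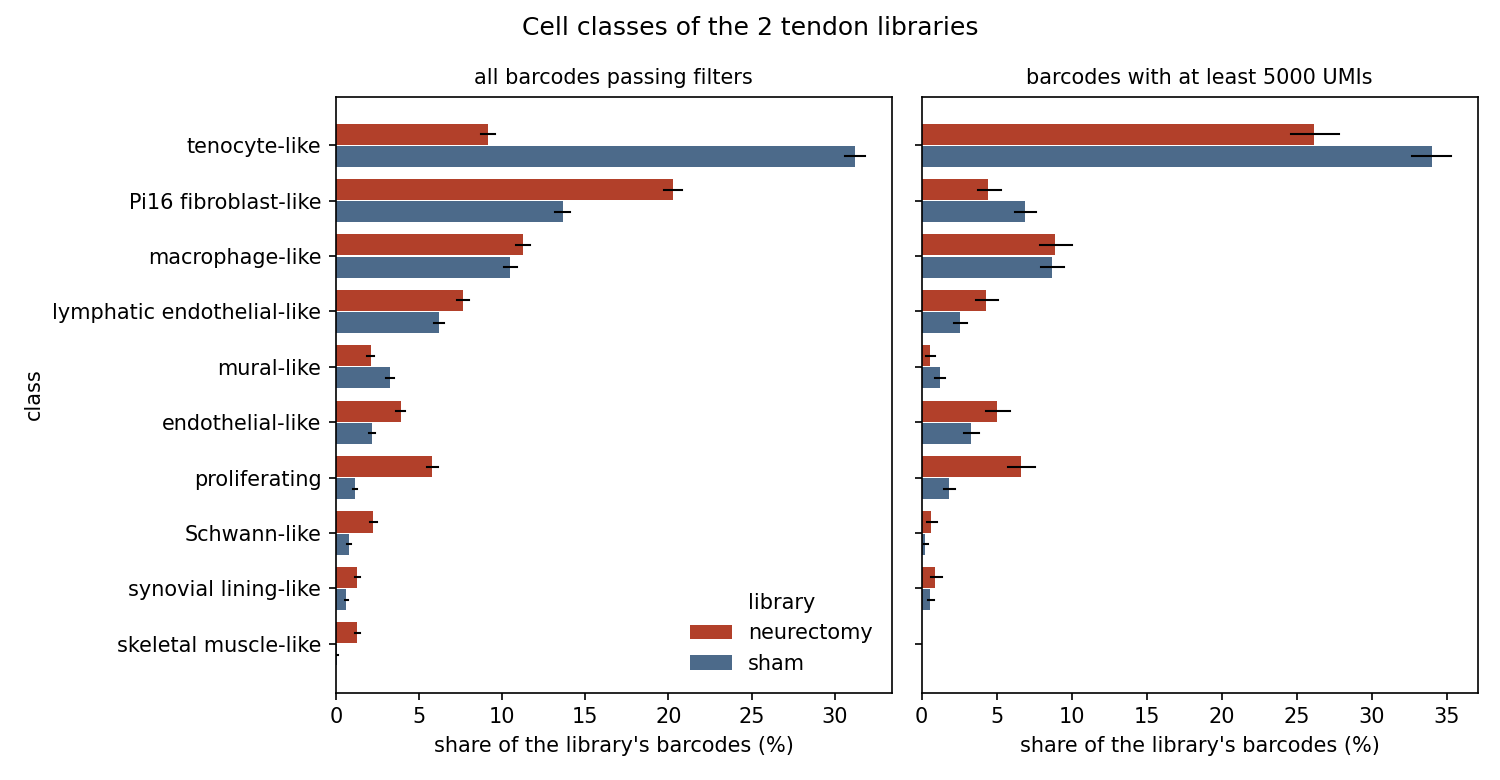
Share of each library's barcodes (%, horizontal axis) in the cell classes named in the text (vertical axis), neurectomy in red and sham in blue, with exact 95% binomial intervals as lines. The left panel holds all barcodes that passed filters and the right panel those with at least 5000 UMIs, where no skeletal muscle-like cluster formed. The tenocyte-like bars are 9.15% and 31.2% on the left and 26.2% and 34.0% on the right.

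Gene levels within the tenocyte-like class were compared as summed UMIs scaled to the total of the class (CPM) over 1844 neurectomy and 7240 sham barcodes. Of 8434 genes that entered, 60 were at least 2-fold higher and 57 at least 2-fold lower in the neurectomy library, as a description of these libraries. Il1rl1 (ENSMUSG00000026069), the receptor for interleukin-33, was at 79.2 against 12.7 CPM, 6.24-fold (5.67 to 6.87). Ccl2 (ENSMUSG00000035385) and Ccl7, chemokines that draw monocytes, were 4.33-fold (3.99 to 4.71) higher and at a log2 ratio of 1.89 (1.72 to 2.06), and Mmp3, a protease that degrades matrix, 1.91 (1.70 to 2.13). Angptl4 (ENSMUSG00000002289), a secreted inhibitor of lipoprotein lipase, was at 36.7 against 4.51 CPM, a log2 ratio of 3.02 (2.80 to 3.25). Uhrf1, which maintains DNA methylation at replication, and Mcm2, part of the replicative helicase, had log2 ratios of 2.56 (2.25 to 2.86) and 1.87 (1.60 to 2.14). Npr3, the clearance receptor for natriuretic peptides, was at 2.04 (1.80 to 2.29), Rrad, a small GTPase of the Ras family, at 1.92 (1.79 to 2.04), Gfra2, the receptor for neurturin, at 1.88 (1.65 to 2.12), and Rgs16, a regulator of G protein signalling, at 1.82 (1.52 to 2.13). The highest log2 ratio, 3.15 (2.71 to 3.61), was that of Acta1 (ENSMUSG00000031972), the actin of skeletal muscle, at 10.6 against 1.19 CPM. Acta1 was also higher in the neurectomy library in the macrophage-like class, at 46.5 against 3.05 CPM.

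Among genes lower in the neurectomy tenocyte-like class, Mstn (ENSMUSG00000026100), which encodes myostatin, was at 11.3 against 89.6 CPM, a log2 ratio of -2.99 (-3.20 to -2.79). Postn (ENSMUSG00000027750), which encodes the matricellular protein periostin, was at 29.0 against 117 CPM, a log2 ratio of -2.02 (-2.15 to -1.89). Slc16a3, a lactate exporter, and Ankrd37, a target of hypoxia-inducible factor, had log2 ratios of -3.14 (-3.53 to -2.79) and -2.50 (-3.00 to -2.03), and Mest, an imprinted gene, -2.45 (-2.89 to -2.04). The other 7 named genes belong to the interferon response: Oasl2 at -3.91 (-4.80 to -3.16), Ifit1 at -3.28, Ifit3 at -2.87, Ifit3b at -2.77, Ddx60 at -2.74, Rtp4 at -2.69 and Ifi203 at -1.99. Ifit3 and Ifit3b are near-identical copies, so the division of counts between them is uncertain. The largest cluster of the class differed: cluster 8 held 36.6% of the neurectomy barcodes and cluster 0 held 70.0% of the sham barcodes, whose median depths were 3606 and 1290.5 UMIs. At Leiden resolution 2 Uhrf1 and Mcm2 lay on the other side of 0. Within the sham library alone, at equal summed UMIs, 302 of 8477 genes were at least 2-fold apart between barcodes with Y-linked UMIs only and with Xist only, against 204 of 8430 between neurectomy barcodes and Xist-only sham barcodes, so gaps of this size also occurred inside a group.

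**Figure D2:**
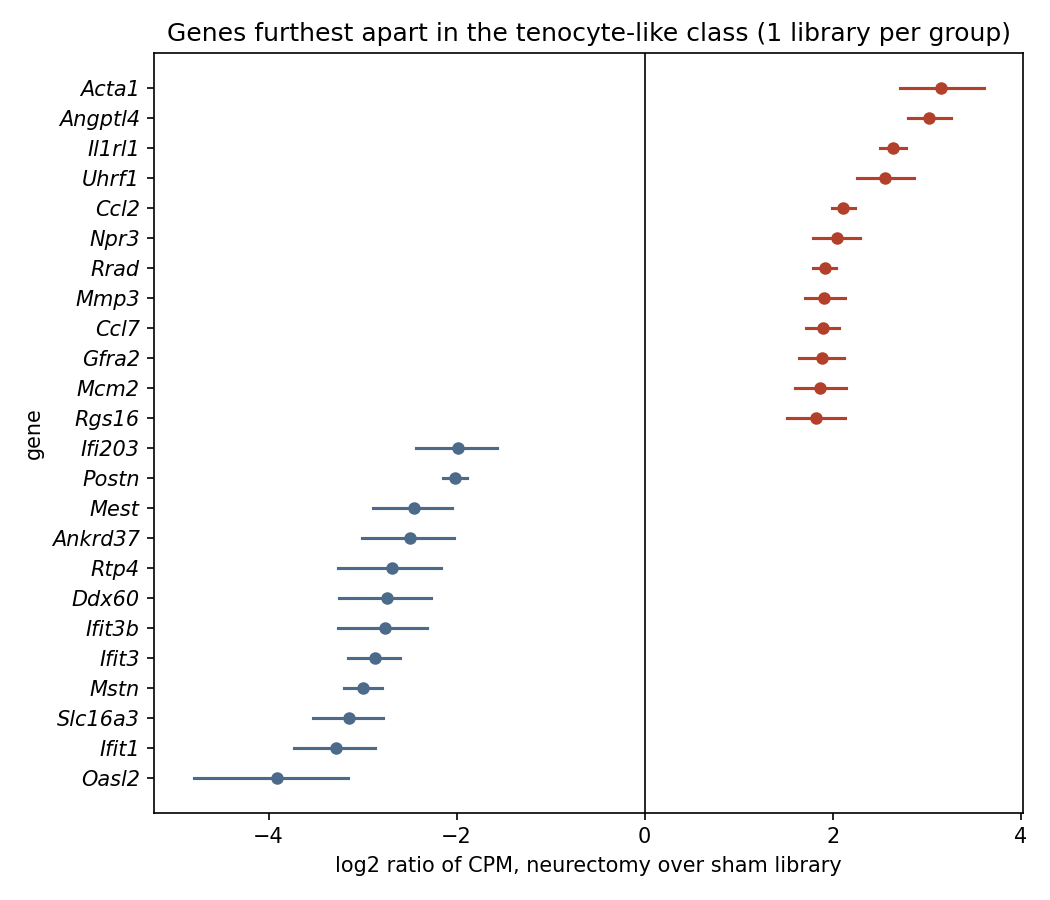
Log2 ratio of CPM, neurectomy over sham library (horizontal axis), of the 24 genes named by the fixed rule in the tenocyte-like class (vertical axis). Points are ratios and lines exact 95% intervals for counting error, with 1 library per group. Angptl4 lies at 3.02, Il1rl1 at 2.64, Mstn at -2.99 and Oasl2 at -3.91.

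Gene lists fixed before the data were examined were read in the same class, each median set against 10000 random lists of the same size and mean expression as a description of these libraries. FGF signalling was the pathway named by the series. The FGF feedback and target genes had a median log2 ratio of 0.00 over 13 measured members, at percentile 35.3 of the random lists, with 6 members whose interval lay above 0, 3 below and 4 holding 0. Among barcodes with at least 5000 UMIs the median was 0.14 over 13 members, at percentile 97.7, with 7 above 0 and 4 below. Ccnd1, a cyclin of the G1 phase, was at 387 against 124 CPM (log2 1.65, 1.60 to 1.70), whereas Spry1, a feedback inhibitor of FGF signalling, was at 32.2 against 50.2 CPM (-0.64, -0.77 to -0.51). The 3 measured FGF receptors had a median of -0.07 (percentile 20.2) and the 3 measured FGF ligands a median of 0.14 (percentile 83.6). Fgfr1 (ENSMUSG00000031565) had a log2 ratio of 0.27 (0.22 to 0.32) and Fgfr2 (ENSMUSG00000030849) -0.07 (-0.14 to 0.01). Of the ligands, Fgf9 was at 72.3 against 49.0 CPM (0.56, 0.46 to 0.66) and Fgf2 at 43.4 against 49.1 CPM (-0.18, -0.30 to -0.06), while the interval of Fgf18 held 0 (0.14, -0.01 to 0.28).

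Genes of the tendon matrix were modestly lower in the neurectomy tenocyte-like class. The list of fibrillar collagen and tendon matrix had a median log2 ratio of -0.21 (percentile 0.00), with 20 of 27 members below 0, 5 above and 2 holding 0. Col1a1 and Col1a2, the chains of type I collagen, had log2 ratios of -0.36 and -0.21, Lum, which encodes the proteoglycan lumican, -0.53, and Col3a1, the chain of type III collagen, -0.21. The tenogenic genes also had a median of -0.21 (percentile 0.01), with 11 of 17 below 0, 5 above and 1 holding 0. Scx, a transcription factor of tendon lineage, was at -0.28, Tnmd, a membrane protein of mature tenocytes, at -0.22 and Bgn, which encodes biglycan, at -0.48, whereas Thbs4 and Fmod, matrix proteins of tendon, were each at 0.27. Col3a1 and Tnmd turned to 0.21 and 0.05 at Leiden resolution 2, where the matrix median was -0.01, and the transcription factor Mkx (-0.13) turned to 0.18 when each barcode was scaled to its own total, to 0.05 at resolution 2 and to 0.01 with doublets kept. Among barcodes with at least 5000 UMIs the medians were -0.20 for the matrix and -0.19 for the tenogenic list, against -0.59 and -0.55 in the macrophage-like, -0.14 and -0.91 in the Pi16 fibroblast-like, -0.13 and -0.62 in the lymphatic endothelial-like and 0.42 and -0.07 in the endothelial-like class. Over all barcodes the medians of these 4 classes were 0.11 and 0.06, -0.26 and 0.28, 0.29 and 0.60, and 0.38 and 0.32. They were -0.02 and -0.31 in the mural-like class and 0.09 and 0.00 in the Schwann-like class.

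Inflammatory and proliferative genes were higher in the neurectomy tenocyte-like class. The inflammatory cytokines and mediators had a median log2 ratio of 0.69 (percentile 100), with 11 of 14 members above 0 and 3 below. Cxcl1, a chemokine for neutrophils, was at 1.27 (1.19 to 1.36), Vcam1, an adhesion molecule for leukocytes, at 1.06 (0.94 to 1.17) and Tnfaip3, a brake on NF-kappa B, at 1.15 (1.02 to 1.29), whereas Cxcl2, another such chemokine, was at -0.96 (-1.23 to -0.70). All 8 measured cell cycle genes had intervals above 0, with a median of 1.22 (percentile 100), among them Mcm3, Mcm5 and Mcm6 at 1.63, 1.71 and 1.50. At Leiden resolution 2 Mcm3 and Mcm5 lay on the other side of 0. The apoptosis genes had a median of 0.21 (percentile 99.7), with 10 of 16 above 0 and 1 below, and the unfolded protein response genes 0.26 (percentile 99.9), with 12 of 15 above 0 and 2 below. The endoplasmic reticulum chaperones Hspa5 and Calr were at 0.30 and 0.38. Stress and immediate-early genes had a median of 0.00 (percentile 22.7), with 9 of 24 above 0 and 12 below.

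Interferon and hypoxia genes were lower in that class. The interferon response list had a median log2 ratio of -1.18 (percentile 0.00), with 7 of 9 measured members below 0, 1 above and 1 holding 0, and the antigen presentation genes -0.36 (percentile 0.45), with 4 of 4 below 0. The hypoxia and glycolysis genes had a median of -0.41 (percentile 0.00), with 13 of 15 below 0 and 2 above. Bnip3, a mitophagy receptor, was at -1.67 (-1.82 to -1.52), Slc2a1, a glucose transporter, at -1.43 (-1.62 to -1.25) and Vegfa, an angiogenic factor, at -1.19 (-1.37 to -1.02). The Wnt pathway genes had a median of -0.09 (percentile 5.74), with 4 of 10 above 0 and 5 below. Over all barcodes an unnamed cluster led by interferon genes, with 2 neurectomy and 225 sham barcodes, is not part of the median of -1.18. The interferon median was -0.25 over 7 members at Leiden resolution 2 and -3.15 over 14 members among barcodes with at least 5000 UMIs, where 112 sham and 5 neurectomy barcodes formed a cluster led by interferon genes. Against sham barcodes with Y-linked UMIs only, at that depth, the interferon median was -0.31 over 6 members and the hypoxia median -0.02.

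Acta1 was higher in the neurectomy library in the other classes given here as well. It was at 33.1 against 2.90 CPM in the Pi16 fibroblast-like class and at 62.0 against 1.33 CPM in the lymphatic endothelial-like class, at 40.3 against 1.26 CPM in the mural-like class and at 47 against 0 UMIs in the Schwann-like class, and in the endothelial-like class it was at least 40.6-fold higher than the limit of 3 counts. In the Pi16 fibroblast-like class, Tnnc2, Myl1, Mylpf and Tnni2, parts of the contractile apparatus, had log2 ratios of 4.04, 3.84, 3.50 and 3.17, followed by Grid1, a glutamate receptor subunit, at 2.35 (2.16 to 2.55). Lower there were Car3, a carbonic anhydrase (-2.89), Serpinb7, a protease inhibitor (-2.71), Adamts19, a metalloprotease (-2.64), C7, a complement component (-2.48, -2.67 to -2.30), Isg15, an interferon-induced modifier (-2.17, -2.56 to -1.80), and Grin2a, a glutamate receptor subunit (-2.13). Car3 turned to 3.11 with at least 1000 genes per barcode and to 3.19 at Leiden resolution 2, and lay above 0 with an interval holding 0 at 5000 UMIs (0.83), clustered without genes 2-fold apart (0.07) and with doublets kept (0.06). Sfrp4, a secreted modulator of Wnt signalling, was at 481 against 208 CPM in this class (1.21, 1.16 to 1.27), and the interferon response list had a median of -0.62 over 14 members (percentile 0.00), with 9 below 0 and 2 above. Among barcodes with at least 5000 UMIs that median was 0.02 over 10 members (percentile 62.0), with 3 above 0 and 3 below, and it was 0.06 with at least 1000 genes and 0.15 at Leiden resolution 2, so the lower level did not hold there.

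In the endothelial-like class, the fixed list of endothelial activation and angiogenesis had a median log2 ratio of 0.42 over 17 members (percentile 100), with 8 above 0 and 3 below, and 0.24 over 18 members among barcodes with at least 5000 UMIs. Of single genes, Sele, which encodes E-selectin, was at 293 against 85.5 CPM (log2 1.78, 1.54 to 2.02), Selp, which encodes P-selectin, at 712 against 323 CPM (1.14, 1.01 to 1.27), Vcam1 at 79.2 against 22.0 CPM (1.85, 1.38 to 2.35), Ackr1, a chemokine receptor of venules, at 157 against 67.7 CPM (1.21, 0.93 to 1.50), and Il6, which encodes interleukin-6, at 32.4 against 8.41 CPM (1.95, 1.19 to 2.78). The inflammatory list had a median of 0.41 over 13 members (percentile 99.9), with 6 above 0 and 2 below, but -0.05 with at most 5% mitochondrial UMIs and 0.05 when each barcode was scaled to its own total. Besides Acta1, the muscle genes Tnnc2, Tnnt3, Myl1 and Tnni2 were named, with 1 to 4 sham UMIs each and log2 ratios of 6.26, 6.19, 4.62 and 4.01. The leukocyte genes Ptprc (-2.68), Cd74 (-2.57), Lyz2 (-2.33) and H2-Aa (-2.32) and the urea transporter Slc14a1 (-3.26) were lower, and Lyz1, which shares sequence with Lyz2, was at least 20.6-fold lower against the limit of 3 counts. Cluster 15 was the largest of the class in each library, with 87.7% of the neurectomy barcodes and 49.0% of the sham barcodes. Selp and Sele were among the leading genes of that cluster. Over all barcodes, the ratios of the activation list and of these single genes therefore cannot be told apart from the makeup of the class.

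In the lymphatic endothelial-like class the rule named Pvalb, Tnnc2, Ckm, Acta1, Col22a1 and Tnni2, genes of muscle or its junction with tendon, with log2 ratios from 5.02 to 6.42. The genes Dsp (-1.90), Mmp19 (-1.83), Ifit1 (-1.74), Myl9 (-1.72), Ifi44 (-1.67) and Isg15 (-1.63) were lower, and Myl9 turned to 3.74, from 8 counts, among barcodes with at least 5000 UMIs. Inhba, a subunit of activin A, was at 166 against 27.4 CPM (2.60, 2.36 to 2.85). The inflammatory list had a median of 0.74 over 17 members (percentile 100), with 13 above 0 and 2 below, and the interferon list -0.78 over 13 members (percentile 0.00), with 12 below 0. In the mural-like class, Edn1, which encodes the vasoconstrictor endothelin 1, had a log2 ratio of 1.95 (1.56 to 2.36), and Ramp1, a subunit of the receptor for calcitonin gene-related peptide (CGRP), was at 16.0 against 70.7 CPM (-2.15, -2.91 to -1.46). Mctp1 was at 186 against 46.3 CPM and Rad51b at 48.7 against 12.2 CPM, Tox and Mdfic2 had log2 ratios of 1.97 and 1.90 and Acta1 of 5.00, while Col19a1, Rnd2 and the class II antigen presentation genes H2-Aa, H2-Ab1 and H2-Eb1 lay between -3.84 and -2.24. H2-Eb1 turned to 2.20, from 15 counts, when clustered without genes at least 2-fold apart. The interferon list had a median of 0.49 over 13 members in this class (percentile 99.99), with 6 above 0 and 7 holding 0, the opposite direction to the tenocyte-like class, and the inflammatory list 0.62 over 11 members (percentile 100).

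In the Schwann-like class, of 455 neurectomy and 183 sham barcodes, Ngfr, the low-affinity neurotrophin receptor found on immature and denervated Schwann cells, was at 93.0 against 10.9 CPM, a log2 ratio of 3.09 (1.80 to 4.76) from 74 and 5 UMIs. The ratios of Pcdh11x (5.71), Unc5c (5.27), Rgs5 (4.63), Tafa2 (4.35), Car10 (4.16) and Sh3gl3 (4.08) rested on 1 to 3 sham UMIs each. Spp1, which encodes osteopontin, was at 95.5 against 906 CPM (-3.25, -3.62 to -2.89), and Ibsp (-5.58, from 2 and 55 UMIs), Ptprz1 (-3.83), Rims1 (-3.80), Fgl2 (-3.58) and H1f5 (-3.38) were also lower. Spp1 and Ibsp were also the leading genes of an unnamed cluster that scored nearest to chondrocytes and osteoblasts, with 297 neurectomy and 1105 sham barcodes, and Spp1 was lower in the tenocyte-like class as well (170 against 369 CPM). In the macrophage-like class, Retnla, a gene of alternatively activated macrophages, was at 206 against 42.5 CPM (2.28, 2.13 to 2.44), Il10, an anti-inflammatory cytokine, at 104 against 42.8 CPM (1.28, 1.10 to 1.45) and Il1b, a pro-inflammatory cytokine, at 189 against 101 CPM (0.90, 0.78 to 1.02). The muscle genes Pvalb, Ckm, Tnnc2, Acta1, Myl1 and Mylpf had log2 ratios from 3.59 to 6.82, and Retnlg (-6.22, from 1 neurectomy UMI), Mstn (-3.28), Ifi213 (-3.24), Plet1 (-2.32), Mx1 (-2.13) and Ifit3 (-2.10) were lower. The interferon list had a median of -0.78 over 18 members in this class (percentile 0.00), the inflammatory list 0.27 over 23 (percentile 99.99) and the cell cycle list 0.61 over 20 (percentile 100), with 17 above 0. Among macrophage-like barcodes with at least 5000 UMIs these medians were -0.68 over 18, 0.08 over 18 (percentile 87.2, with 8 above 0 and 8 below) and 0.20 over 9 (percentile 97.3). The sex difference of the pools and the muscle transcripts hold for each of these classes.

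The lists not yet given in these classes had the following medians. The FGF feedback and target genes were at 0.12 in the Pi16 fibroblast-like (percentile 99.5), -0.12 in the endothelial-like (11.4), 0.33 in the lymphatic endothelial-like (100), -0.11 in the mural-like (11.6), 0.41 in the Schwann-like (94.1) and 0.19 in the macrophage-like class (99.1). Among barcodes with at least 5000 UMIs they were at -0.01 in the Pi16 fibroblast-like, 0.01 in the endothelial-like, 0.30 in the lymphatic endothelial-like (percentile 99.8) and 0.20 in the macrophage-like class (percentile 99.0). The mural-like median turned to 0.20 when each barcode was scaled to its own total, and the Schwann-like one to -0.03 with the lower count filter. The inflammatory list was at 0.07 in the Pi16 fibroblast-like class (percentile 96.0), where it was -0.09 at 5000 UMIs with 3 members above 0 and 6 below, and at -0.14 in the Schwann-like class (percentile 17.2). The interferon list was at 0.00 in the endothelial-like (percentile 46.9) and -0.33 in the Schwann-like class (percentile 2.80). The cell cycle list was at 0.30 in the Pi16 fibroblast-like, 0.06 in the endothelial-like, 0.29 in the lymphatic endothelial-like, 0.18 in the mural-like and -0.19 in the Schwann-like class.

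FGF receptors were described by class because the series names them. Fgfr1 was highest in the Pi16 fibroblast-like class, at 513 (502 to 524) CPM in the neurectomy library and 488 (479 to 498) CPM in the sham library. In the tenocyte-like class it was at 292 (284 to 299) against 242 (237 to 246) CPM. A UMI of Fgfr1 was seen in 63.1% and 41.9% of tenocyte-like barcodes. After thinning to 2000 UMIs, which left out 670 neurectomy and 4790 sham barcodes, the shares were 41.3% (38.5 to 44.2%) and 37.2% (35.3 to 39.1%). Fgfr1 was lowest among these classes in endothelial-like barcodes, at 85.3 and 60.3 CPM and 15.5% and 12.7% of thinned barcodes, whose median depths were 1698 and 2063.5 UMIs. In macrophage-like barcodes Fgfr1 was at 253 and 265 CPM and in 33.4% and 35.0% of thinned barcodes, so it did not set tenocyte-like barcodes apart. Tendon transcripts were also found outside tenocyte-like barcodes, with Col1a1 at 7188 and 8550 CPM in the macrophage-like class. Among macrophage-like barcodes with at least 5000 UMIs, Col1a1 was at 1903 and 2832 CPM and Fgfr1 at 273 and 286 CPM, so Fgfr1 was not lower there as Col1a1 was. Fgfr2 was at 101 and 106 CPM in tenocyte-like, 104 in both libraries' Pi16 fibroblast-like and 130 and 120 CPM in endothelial-like barcodes, and in the Schwann-like class it was at 201 (171 to 235) against 85.2 (60.6 to 116) CPM. Fgfr3 was near 1 CPM in tenocyte-like barcodes (1.03 and 1.42) and at 22.3 and 21.0 CPM in endothelial-like barcodes.

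The ganglia were read to ask which of their cells held Fgf1, an FGF that signals through all FGF receptors. Fgf1 was at 201 (182 to 222) CPM in mural-like barcodes, 156 (151 to 162) CPM in myelinating Schwann-like barcodes and 151 (149 to 153) CPM in neurons, and the next named class, erythroid-like, was at 20.9 CPM. Neurons were 3470 barcodes with a median of 47607 UMIs, and 73.5% of them held an Fgf1 UMI. After thinning to 2000 UMIs, which left out 373 neurons, 24.3% (22.8 to 25.9%) did, against 27.1% (25.7 to 28.5%) of myelinating Schwann-like and 29.0% (25.1 to 33.2%) of mural-like barcodes, with 3305 and 201 left out. Unthinned, 28.7% and 30.3% of those classes held Fgf1. Macrophage-like barcodes, taken as background, were at 5.97 CPM, with Fgf1 in 1.95% of barcodes and 1.17% of thinned ones at a median depth of 3366 UMIs. Satellite glia-like barcodes, the glia around neuron cell bodies, were at 17.5 CPM and fibroblast-like barcodes at 20.8 CPM. Other FGF ligands had other distributions. Fgf13 (996 CPM) and Fgf12 (430 CPM), members that act inside the cell on sodium channels, were highest in neurons, Fgf7, a ligand made by stromal cells, was at 82.9 CPM in myelinating Schwann-like and 73.2 CPM in fibroblast-like barcodes, and Fgf2 was at 65.8 CPM in non-myelinating Schwann-like barcodes. The mural-like level was 54.0 (34.6 to 80.4) CPM, from 24 counts, with at most 5% mitochondrial UMIs.

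**Figure D3:**
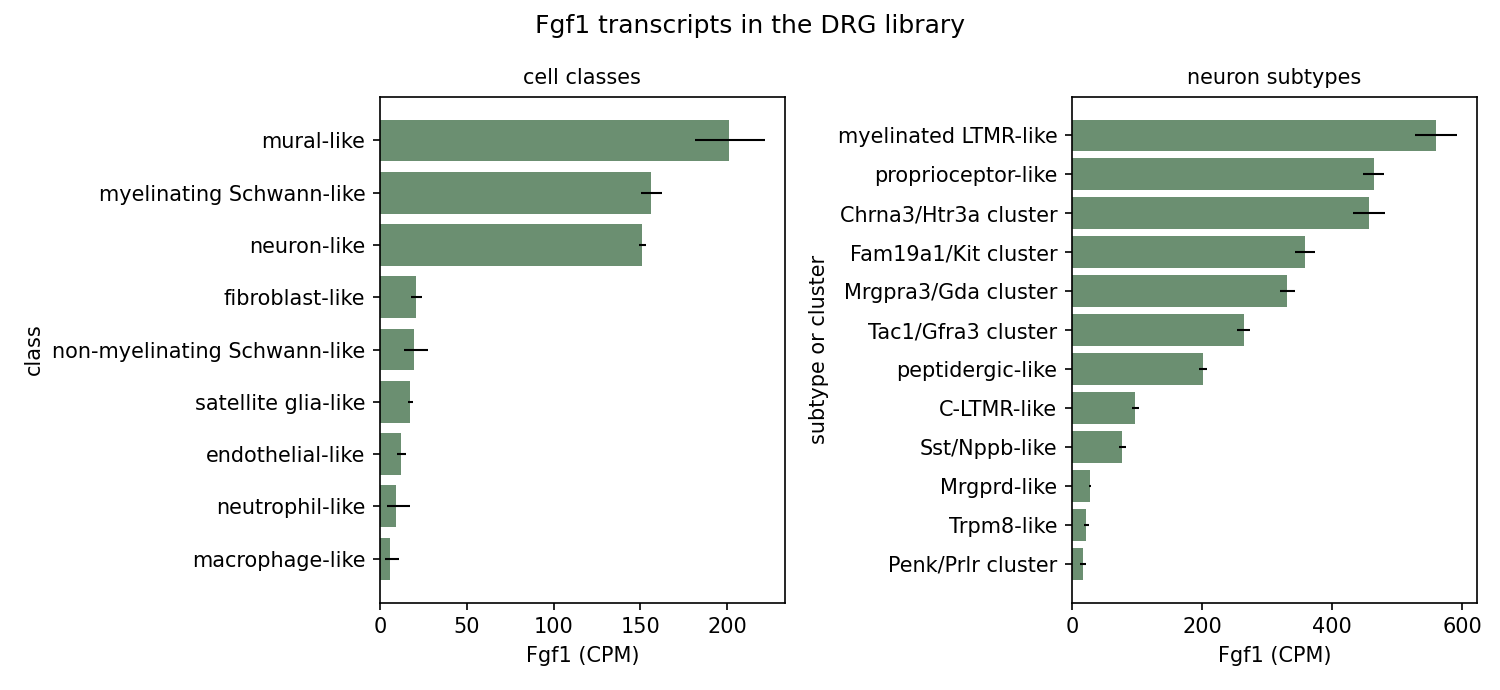
Fgf1 level in CPM (horizontal axes) in the DRG library, by cell class on the left and by neuron subtype or unnamed cluster, called by leading genes, on the right (vertical axes). Bars are levels and lines exact 95% Poisson intervals. Mural-like, myelinating Schwann-like and neuron-like classes stand at 201, 156 and 151 CPM, and proprioceptor-like neurons at 464 against 28.2 CPM in Mrgprd-like neurons.

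Fgf1 differed strongly between neuron subtypes. It was at 559.6 (528 to 593) CPM in the 47 neurons resembling myelinated low-threshold mechanoreceptors (LTMR, touch-sensing neurons), and at 464 (448 to 480.0) CPM in proprioceptor-like neurons, named after the neurons that sense muscle and tendon stretch. That name led the next, myelinated LTMR, by scores of 2.41 and 1.91, close to the least lead of 0.5, and Calca was at 2831 CPM in these neurons, so it is uncertain. Peptidergic-like neurons, nociceptors that release neuropeptides, were at 201 (196 to 207) CPM. C-LTMR-like neurons, unmyelinated touch-sensing neurons, were at 97.9 CPM, Sst/Nppb-like neurons, which mediate itch, at 77.4 CPM, Mrgprd-like neurons, nociceptors of the skin, at 28.2 (26.8 to 29.7) CPM and Trpm8-like neurons, which sense cold, at 21.9 CPM. Clusters left unnamed spanned the same range, with 456 CPM in a cluster led by Chrna3 and Htr3a, 359 CPM in a cluster led by Fam19a1 and Kit, 331 CPM in a cluster led by Mrgpra3 and Gda, 264 CPM in a cluster led by Tac1 and Gfra3 and 16.6 CPM in a cluster led by Penk and Prlr. Fgf12 was at 2132 CPM in the cluster led by Fam19a1 and Kit and at 1037 CPM in C-LTMR-like neurons. Among secreted signals, Bdnf, a neurotrophin, was at 480.2 CPM in Sst/Nppb-like and 393 CPM in peptidergic-like neurons, Gal, which encodes galanin, at 589 CPM in peptidergic-like and 397 CPM in Trpm8-like neurons, and Nrg1, a growth factor for Schwann cells, at 358 CPM in proprioceptor-like neurons. Across the whole neuron class, Calca, which encodes CGRP, was at 2688 CPM and Tac1, which encodes substance P, at 1306 CPM, and both were among the markers used to name peptidergic-like neurons. Unnamed clusters held 38.7% of the neurons.

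The vector transcript was used to ask which neurons carried it after the injection into the tendon sheath. The route by which it reached the ganglia was not tested. The feature table lists 4 vector features without saying which encodes the reporter: AAV_gene1 had 12601 UMIs in 472 barcodes, and the other 3 had 0. A UMI of AAV_gene1 was found in 361 of 3470 neurons (10.4%, 9.41 to 11.5%) and in 95 of 18298 other barcodes (0.519%, 0.420 to 0.634%), which are shallower. Among neurons with at least 2000 UMIs, the traced share was 37.5% (29.4 to 46.2%) in the cluster led by Fam19a1 and Kit and 27.7% (21.4 to 34.6%) in proprioceptor-like neurons. It was 10.3% (7.87 to 13.3%) in peptidergic-like, 9.02% (6.94 to 11.5%) in Mrgprd-like, 5.86% (3.57 to 9.01%) in C-LTMR-like and 4.52% (2.09 to 8.41%) in Trpm8-like neurons. In the classes other than neurons and fibroblasts the vector was at 0.989 CPM, from 61 UMIs. If background UMIs grow with depth, which was not tested, this level gives expected shares of 4.36%, 3.71%, 4.32%, 7.41%, 4.80% and 3.27% in that order. On that assumption the intervals of the Mrgprd-like, C-LTMR-like and Trpm8-like shares held the expected share. With at least 2 vector UMIs the shares were 31.6%, 21.8%, 6.51%, 4.59% (3.12 to 6.48%), 4.01% (2.15 to 6.76%) and 2.51% (0.821 to 5.77%). They lay above the at most 0.313% expected from that level. Fibroblast-like barcodes, left out of that level, held 226 of the 287 vector UMIs outside neurons, at 25.9 CPM. Shares expected from a background that includes them would be higher and were not computed, so background stays open for the lower shares. Traced neurons, also those with at least 2 UMIs, may therefore include some from background. Of the groups not yet given, myelinated LTMR-like neurons were traced at 21.3% (10.7 to 35.7%) and the cluster led by Mrgpra3 and Gda at 20.3% (14.3 to 27.4%). With at least 2 vector UMIs they were at 10.6% and 15.8%. Fgf1 was at 221 CPM in the 355 traced neurons and 142 CPM in the 2742 untraced ones, a ratio of 1.56 (1.51 to 1.61). The FGF ligands had a median log2 ratio of 0.64 over 7 measured members (percentile 100), with Fgf9 at 2.46-fold (2.13 to 2.85) and Fgf12 at 1.39-fold but Fgf13 at 0.971-fold and Fgf14 at 0.775-fold. Within a subtype Fgf12 was at 0.709-fold in proprioceptor-like, 0.965-fold in C-LTMR-like and 1.16-fold in peptidergic-like neurons. The neuropeptides had a median of -0.45 over 11 (percentile 0.00), with Nppb, a peptide of itch, at 0.350-fold and Penk, which encodes enkephalins, at 0.125-fold, whereas Calca, Calcb and Nmb were at 1.16, 1.05 and 1.05-fold. Tac1 was at 0.730-fold, and within clusters it ran both ways, from 0.397-fold in the cluster led by Chrna3 and Htr3a to 3.02-fold in the cluster led by Fam19a1 and Kit. It was at 26.2-fold in the unnamed neuron cluster 20, led by Rgs5 and Kcnq3, from 207 UMIs in 10 traced and 31 UMIs in 41 untraced neurons. Myelinated LTMR-like neurons, also led by these genes, were at 1.99-fold. Medians were 0.03 for the growth factors of DRG neurons (percentile 84.0), -0.10 for the sensory ion channels and receptors (percentile 1.38) and -0.16 for the nerve injury genes (percentile 0.69). Gap43, a protein of growing axons, was however at 1.57-fold (1.54 to 1.60), and within subtypes it varied. It was at 0.992-fold in proprioceptor-like and 1.02-fold in peptidergic-like neurons. It was higher in Mrgprd-like (1.33), myelinated LTMR-like (1.49) and Sst/Nppb-like neurons (1.30). The clusters led by Mrgpra3 and Gda (1.18) and by Fam19a1 and Kit (1.15) were also higher, and those led by Tac1 and Gfra3 (0.886) and cluster 20 (0.881) lower. Within a subtype or cluster with at least 10 traced neurons the Fgf1 ratio ran from 0.867 (0.746 to 1.00) in the cluster led by Tac1 and Gfra3 to 1.32 (0.943 to 1.81) in the unnamed neuron cluster 20. It was 1.07 (0.99 to 1.15) in proprioceptor-like, 1.05 (0.96 to 1.15) in peptidergic-like and 1.15 (0.97 to 1.36) in Mrgprd-like neurons and 0.943 (0.865 to 1.03) in the cluster led by Fam19a1 and Kit. In the cluster led by Chrna3 and Htr3a it was 1.20 (1.04 to 1.38), from 12 traced neurons, and the intervals of the other groups held 1. Proprioceptor-like neurons were 14.6% of traced and 4.96% of untraced neurons, and the cluster led by Fam19a1 and Kit 14.4% and 3.10%. Mrgprd-like neurons, low in Fgf1, were 16.6% and 21.7%. The pooled Fgf1 ratio of 1.56 thus largely followed subtype makeup. The FGF ligand median was not computed within subtypes.

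**Figure D4:**
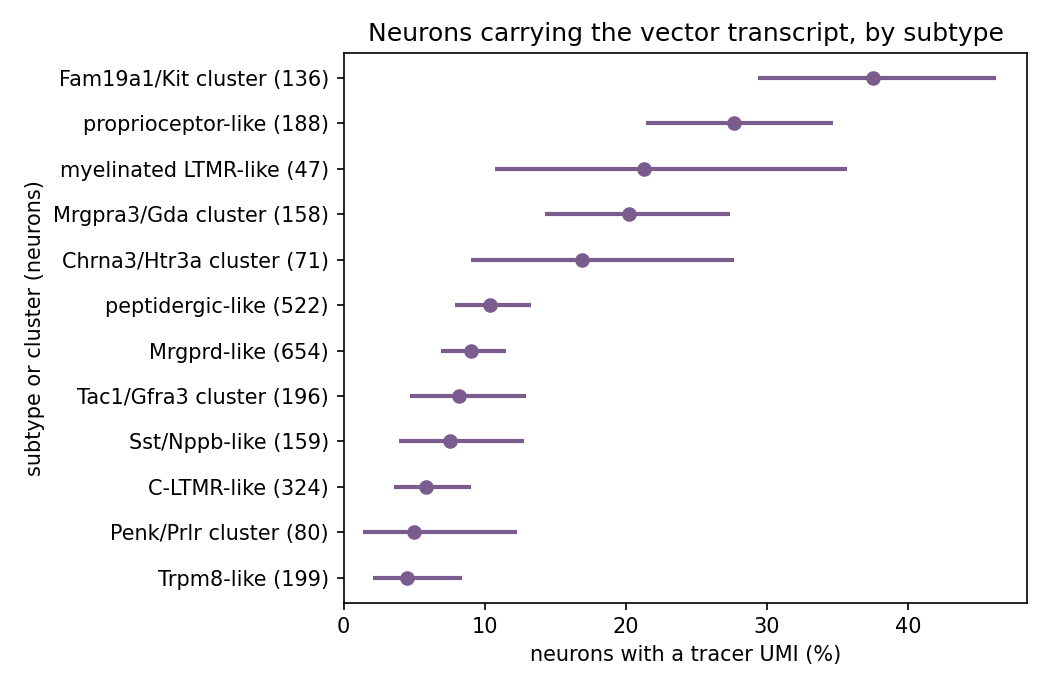
Share of neurons with at least 1 UMI of AAV_gene1 (%, horizontal axis) in each neuron subtype or unnamed cluster called by its leading genes (vertical axis, number of neurons in brackets). Points are shares and lines exact 95% binomial intervals. The named subtypes and 5 unnamed clusters are drawn, counting neurons with at least 2000 UMIs. Of the 9 unnamed clusters not drawn, 5 held no traced neuron at that depth, and clusters 14, 20, 21 and 26 held 7.06%, 19.6%, 10.6% and 14.8%. Among those drawn, the shares run from 37.5% in the cluster led by Fam19a1 and Kit and 27.7% in proprioceptor-like neurons to 4.52% in Trpm8-like neurons.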

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

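The alternatives on barcodes with at least 5000 UMIs, on unnamed clusters added to the nearest class, on clustering without genes at least 2-fold apart, on Xist-only sham barcodes and on neurons with at least 10000 UMIs were chosen after seeing the data, and the cause of the moves below was not tested unless given. All 155 named genes kept their direction under the other scalings, but the naming rule required this of the genes it picked. The lower count filter changes which genes enter and not a gene's ratio, so it could turn none of them. Of the 155, 150 kept their direction when each barcode was scaled to its own total, 152 with doublets kept and 152 clustered without genes 2-fold apart. The direction was kept by 131 of 140 at Leiden resolution 2 and by 125 of 126 with at least 1000 genes. It was kept by 124 of 126 with at most 5% mitochondrial UMIs and by 123 of 125 at 5000 UMIs. No paired analysis was possible because each group has 1 library. Depth limits the Schwann-like and mural-like classes, which had too few barcodes for some settings: both with at least 1000 genes, at most 5% mitochondrial UMIs and at least 5000 UMIs, and Schwann-like at resolution 2.

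The tenocyte share ratio of 0.293 was 0.545 with at least 1000 genes, 0.265 with at most 5% mitochondrial UMIs, 0.258 with doublets kept, 0.770 at 5000 UMIs and 0.260 clustered without genes 2-fold apart. The Pi16 ratio of 1.49 reversed to 0.577 with at least 1000 genes, 0.658 at resolution 2 and 0.646 at 5000 UMIs. It was 1.11 with at most 5% mitochondrial UMIs and 1.13 with doublets kept. At 5000 UMIs a cluster nearest to that class stayed unnamed. It scored 2.315 for Pi16 and 2.276 for stromal fibroblast markers, so its place is uncertain. Clusters that the lead, the need for a leading marker or the lowest mean left unnamed were added to the nearest class at 5000 UMIs. The tenocyte ratio was then 0.789, the Pi16 ratio 1.40, the proliferating ratio 3.58 and the lymphatic ratio (1.23) reversed to 0.717. Clusters led by genes of another class were not added. The cluster behind that reversal scored nearly the same for tenocytes, and 29.1% of its sham barcodes held both Xist and a Y-linked UMI. The proliferating ratio of 5.09 was 4.31 with doublets kept, 3.58 at 5000 UMIs and 3.91 clustered without genes 2-fold apart. The erythroid-like ratio of 0.339 reversed to 4.52 with at least 1000 genes, the synovial lining-like ratio to 0.623 with at most 5% mitochondrial UMIs and 0.784 with doublets kept, and the macrophage ratio to 0.924 with doublets kept.

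In the tenocyte-like class the 117 genes at least 2-fold apart became 1737 of 18259 with the lower count filter, which admits more genes of few counts, and 177 of 8372 against Xist-only sham barcodes. The interferon median of -1.18 was -1.45 without mitochondrial, ribosomal, haemoglobin and Malat1 UMIs in the total, -1.88 with the lower filter, -2.81 with at least 1000 genes, -0.25 at resolution 2, -3.15 at 5000 UMIs, -2.43 clustered without genes 2-fold apart and -3.31 against Xist-only sham barcodes. The inflammatory median of 0.69 was 0.32 with the lower filter, 0.38 as a mean over barcodes, 0.90 with at least 1000 genes, 0.89 at resolution 2 and 0.94 against Xist-only sham barcodes. The FGF feedback median of 0.00 was 0.18 with the lower filter, 0.14 with at least 1000 genes, 0.14 at 5000 UMIs and 0.22 against Xist-only sham barcodes. The matrix median of -0.21 was -0.0949 as a mean over barcodes, -0.10 with at most 5% mitochondrial UMIs and -0.0113 at resolution 2. Mkx reversed to 0.18 as a mean over barcodes and lay above 0 with an interval holding 0 at resolution 2 and with doublets kept, and Col3a1 to 0.21 and Tnmd to 0.0484 at resolution 2. The tenogenic median of the Pi16 class (0.28) reversed to -0.248 as a mean over barcodes, -0.482 with at least 1000 genes, -0.157 with doublets kept, -0.141 at resolution 2 and -0.913 at 5000 UMIs, that of the lymphatic class (0.60) to -0.617 at 5000 UMIs, and that of the endothelial class (0.32) to -0.215 with at least 1000 genes, -0.322 at resolution 2 and -0.208 clustered without genes 2-fold apart. The matrix median of the macrophage class (0.11) reversed to -0.267 as a mean over barcodes and -0.594 at 5000 UMIs, that of the endothelial class (0.38) to -0.137 at resolution 2 and that of the lymphatic class (0.29) to -0.196 as a mean over barcodes. In other classes Car3 (Pi16) reversed to 3.11 with at least 1000 genes and 3.19 at resolution 2, Myl9 (lymphatic) to 3.74 at 5000 UMIs, and H2-Eb1 (mural) to 2.20 clustered without genes 2-fold apart.

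Thinned to 1000 UMIs, Fgfr1 was seen in 24.8% and 19.9% of neurectomy and sham tenocyte-like barcodes and Fgf1 in 13.7% of neurons. With at most 5% mitochondrial UMIs, Fgf1 was at 122 CPM in neurons (22.4% of thinned ones), 165 CPM in myelinating Schwann-like, 54.0 CPM in mural-like, 241 CPM in peptidergic-like and 26.7 CPM in Mrgprd-like barcodes. Proprioceptor-like neurons were at 515 CPM with at least 1000 genes and 516 CPM at 10000 UMIs, peptidergic-like neurons at 235 CPM with doublets kept, 245 CPM at resolution 2 and 238 CPM at 10000 UMIs, and Mrgprd-like neurons at 31.1 CPM at 10000 UMIs. With at least 2 tracer UMIs, 7.32% of neurons were traced and the Fgf1 ratio was 1.70.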

Other observations

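Tests chosen after the result was seen were those on barcodes of few UMIs, on the sex of the pools for the interferon list, on free muscle RNA and on differences between mice within a pool. The ganglia held growth factors outside the FGF family in classes other than neurons. Ptn, which encodes the heparin-binding factor pleiotrophin, was at 3600.5 CPM in satellite glia-like and 2039 CPM in endothelial-like barcodes of the DRG library. Hbegf, a ligand of the epidermal growth factor receptor, was at 2638 CPM in endothelial-like barcodes, Spp1 at 1415 CPM in myelinating Schwann-like barcodes and Pdgfa, a platelet-derived growth factor, at 485 CPM in mural-like barcodes. Atf3, a transcription factor of the injury response, was at 1977 CPM in non-myelinating Schwann-like and 626 CPM in myelinating Schwann-like barcodes. Of the 287 vector UMIs outside neurons, 226 lay in fibroblast-like barcodes (25.9 CPM, 22.6 to 29.5), against 0 in the 704 mural-like barcodes.

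Tendon classes also held FGF ligands. Fgf1 (ENSMUSG00000036585) was at 73.9 (59.3 to 91.1) CPM in the mural-like class of the neurectomy library and 104 (91.0 to 117) CPM in that of the sham library, at 47.7 and 93.9 CPM in the Schwann-like class, at 19.1 and 18.4 CPM in the Pi16 fibroblast-like class and at 6.29 and 5.51 CPM in the tenocyte-like class, and the direction between the libraries in the mural-like and Schwann-like classes turned when each barcode was scaled to its own total. Fgf7 was at 176 and 158 CPM and Fgf10, another stromal ligand, at 51.0 and 44.4 CPM in the Pi16 fibroblast-like class. In the sham library, 278 of 5255 barcodes with at least 5000 UMIs (5.29%) held both Xist and a Y-linked UMI, against 9 of 2920 in the neurectomy library. Of the 278, 86 lay in the unnamed cluster between the lymphatic and tenocyte classes (29.1% of its sham barcodes) and 52 in the mast-like cluster (24.9%). Tenocyte-like sham barcodes of male type and female type differed in named genes. Among tenocyte-like barcodes with at least 5000 UMIs, Angptl4 had a log2 ratio of 2.22 and Mstn 1.89, Y-only over Xist-only sham barcodes, and Vegfa -1.24.

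The tenocyte-like class was a smaller share of the neurectomy library. Barcodes of few UMIs as the whole cause were argued against by the ratio among barcodes with at least 5000 UMIs, which stayed below 1 at 0.770 (0.707 to 0.839), although most of the gap seen at 0.293 was gone at that depth. Clustering on the genes at least 2-fold apart in the tenocyte-like class was argued against by the ratio of 0.260 (0.246 to 0.275) once those genes were left out. Genes apart only in other classes stayed in, and the genes left out were picked within the class in question. The test therefore cannot decide on clustering by other differences between the libraries. The muscle carried in the neurectomy library, the yield of digestion and the neurectomy itself stay open as untested explanations.

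Interferon genes were lower in the neurectomy tenocyte-like class, with a median of -1.18 over all barcodes. That median leaves out an unnamed cluster nearest to the class, led by Rsad2, Ifit3 and Ifit1, with 2 neurectomy and 225 sham barcodes. It therefore depends on the naming thresholds. Sex of the pooled mice as the whole cause was argued against, since the list's median was -3.31 over 15 members against Xist-only sham barcodes. With a count of at least 10 and no minimum CPM, Y-only sham barcodes were at -2.70 over 18 members against Xist-only sham barcodes. Neurectomy barcodes were there at -0.31 over 14 members against Y-only and -3.25 over 18 against Xist-only sham barcodes. A gap of nearly this size thus also occurred inside the sham library, so a part played by sex stays open. A candidate explanation is a cluster of interferon-high sham barcodes, 112 of which stood at 5000 UMIs or more, and without it the median was -0.32 over 6 members, between the bounds set for this test. With a count of at least 10 and no minimum CPM it was -0.63 over 15 members, past the bound set against that cluster as the cause, with members from -2.39 to 0.94, and against Xist-only sham barcodes outside that cluster it was -0.76 over 15 members, also past it. Whether the pattern lay inside that cluster alone or also outside it cannot be told apart, because the 2 filters fall on different sides of that bound. Of these sham barcodes 105 held Xist only and 3 a Y-linked UMI only (the latter 2.78% of these, against 20.2% in the other tenocyte clusters), so the cluster may come from a part of the pooled mice.

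Named genes of the tenocyte-like class lay apart between the libraries. Sex of the pooled mice as the whole cause was argued against for the 23 genes that entered. All 23 kept their direction with an interval beyond 1.5-fold against Xist-only sham barcodes. Those barcodes were 1349 of the 1785 sham barcodes read there, and the genes had been picked for their gap to the sham library. Against Y-only sham barcodes at equal UMIs only 14 named genes entered, and 13 had an interval beyond 1.5-fold in either direction. That count does not show whether they kept their direction. Between Y-only and Xist-only sham barcodes 14 of 17 had such an interval, so a part played by sex stays open. Free muscle RNA could account for Acta1, the only muscle gene among the named genes, which was 15.2-fold (10.6 to 22.5) higher in the macrophage-like class too. Differences between mice within a pool could account for gaps of this size, since 302 genes were 2-fold apart between male-type and female-type sham barcodes and 204 between neurectomy and Xist-only sham barcodes at equal UMIs. Those sham barcodes also differ in sex and in cluster makeup, with Y-only shares of called barcodes from 2.78% to 60.8% across tenocyte clusters. The 302 genes therefore do not measure differences between mice alone. With 1 library per group, an effect of the neurectomy on the named genes stays open beside such differences.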
